A study of Mus musculus with 7 samples.

How the data were processed

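RNA-seq values of 7 mouse libraries were used, 1 library per group: MEF, day 6 sorted tdTomato-positive cells, Tomato-positive and Tomato-negative OSKM NSC, brain NSC, iPSC and ESC. The deposited values are RPKM per exon, made by the authors, with 1 value per Ensembl exon and library. The labels name CASAVA 1.8.2, Bowtie, TopHat2 2.0.10, bedtools and the mm10 build and give no role for each. Of 279252 exons in the file, 270168 (96.7%) were matched by exon ID to the GENCODE M21 annotation (GRCm38), and 9084 without a match were left out. The value of a gene was the mean of its exon values weighted by exon length, which gave 29686 genes, 21474 of them protein coding. A total of 6724 exons shared at least 1 base with an exon of another gene, on either strand, and were kept, each for 1 gene. Strand was not used, so reads from an overlapping gene on the other strand can count, and reads of near-identical genes such as histone copies cannot be told apart.

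The depth was read from the steps of the values: RPKM times exon length fell on whole multiples that gave a whole number of megareads (M) per library, from 19 M in Tomato-positive OSKM NSC to 58 M in iPSC. Between 96.3% and 96.5% of the values tested were whole read counts at that depth, within 0.01 read plus 1e-05 of the value, for values under 5000 reads. Some exons, 10156 or 3.76%, were not whole in at least 1 library. A value of 0 allows up to 3 reads. All 7 of 7 simulated depths were recovered when this step was tested on simulated data.

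Values were compared as log2((a + 1)/(b + 1)) with a and b in RPKM as deposited. A gene was tested where it reached 2 RPKM in at least 1 of the compared libraries, and was counted at 4-fold or more. Members of the fixed lists were counted at 2-fold or more. A comparison with several libraries on a side counted a gene only where each pair passed in the same direction, and the smaller absolute ratio was used for ranking. There were 10 comparisons. No p-value is given because each group has 1 library, and no batch is named in the labels. Strain differs between the groups and cannot be separated from them. The comparisons, rules, lists, named genes and the alternatives of scaling, pseudocount, floor and exon choice were fixed before the data were examined.

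The genes named are, for each comparison, the 8 highest and 8 lowest by log2 ratio among those past 4-fold, leaving out unnamed gene models, up to 4 members of each fixed list with the largest absolute log2 ratio, and Pou5f1, Sox2, Klf4, Myc, Nanog, Nes, Olig2, Pax6, Thy1, Col1a1 and Mbd3 in every library. A gene outside this rule is said to have been chosen after its values were seen. Some genes that the rule names are not reported here. The 27 fixed lists, with 390 members that were all measured, come from textbook knowledge. They cover reprogramming factors, naive pluripotency, general pluripotency, primed epiblast and germ layers, germ line, epithelial, fibroblast and mesenchymal, neural stem cell, forebrain regional, midbrain and anterior hindbrain regional, Hox cluster, neuron, astrocyte, oligodendrocyte lineage, neural crest, microglia and leukocyte, endothelial, muscle, keratinocyte and trophoblast, proliferation, cell cycle inhibitors and p53 targets, immediate early and heat shock, interferon response, imprinted, glycolysis, Mbd3-NuRD and sex-linked genes. The median of a list was taken over members that reached 2 RPKM in any library, and was ranked among 10000 random lists of the same size drawn from 20 bins of mean level with seed 1.

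The plan foresaw no counting interval for a length-normalized unit. Once the depth was known, 95% exact (Clopper-Pearson) intervals of the ratio of reads were added, from reads recovered over exons that do not overlap each other and hold whole reads. They cover counting error only. Since these exons are a subset of those behind the RPKM, an interval is printed only where it contains the ratio of the RPKM values. The share of summed exon reads in Gm42418 has a Wilson interval. The sum counts a read again in each overlapping exon, so the interval is too narrow. The shares of reference differences were set beside a MEF-like library drawn from the MEF reads with Poisson noise and with dispersions of 0.04 and 0.16, and beside the number shared if the lists were independent.

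The rules were tested on simulated data with 200 changed genes among 29686, drawn with counting noise only. The test therefore cannot show how often single libraries of the same kind differ by 4-fold. At the 4-fold rule 0% of genes simulated at 2-fold, 10% at 4-fold, 97% at 8-fold and 100% at 16-fold were counted for day 6 against MEF, and no unchanged gene was counted. The changed genes were drawn only from those well above 2 RPKM in MEF, so recovery of lower genes was not tested. The alternatives were scaling to equal totals, median-of-ratios scaling, pseudocounts of 0.25 and 4, floors of 0.4 and 8 RPKM and none, the highest exon of each gene, and leaving out shared exons. Exons that do not overlap, and each library of a joint comparison left out in turn, were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.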

Results

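RNA-seq was measured in 7 mouse cell populations used to study the conversion of fibroblasts to neural stem cells with the reprogramming factors Oct4 (Pou5f1), Sox2, Klf4 and Myc (OSKM). The populations were mouse embryonic fibroblasts (MEF), cells sorted as tdTomato positive on day 6 of the conversion, neural stem cells made with OSKM that carried the Nanog-driven Tomato label, such cells without the label, primary neural stem cells (NSC) from embryonic brain, induced pluripotent stem cells (iPSC) and the embryonic stem cell (ESC) line v6.5. In the reporter system Nanog-CreER switches on tdTomato in cells that have expressed Nanog while 4OHT was present, and doxycycline drives OSKM from the Col1a locus. Each population had 1 library and no replicate, so a value has no replicate error and a difference has no test. The depth is not given by the labels and was inferred, in whole megareads (M), from the steps of the values. It was 45 M in MEF, 46 M on day 6, 58 M in iPSC and 41 M in ESC. In Tomato-positive OSKM NSC it was 19 M, in Tomato-negative OSKM NSC 42 M and in brain NSC 27 M. Between 13666 genes on day 6 and 15083 genes in ESC stood at or above 2 RPKM (reads per kilobase of exon, scaled to the depth of the library).

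In the day 6 library Gm42418, a gene model over ribosomal RNA on chromosome 17 chosen after its values were seen, took 8.82% of the summed exon reads. The other libraries had 0.0258% to 0.0657%. Exons of a gene can overlap, and the sum counts a read in each exon it lies in. The share is therefore not a share of the sequenced reads, and its 95% Wilson interval (8.82% to 8.83%) is too narrow. The 10 most abundant genes took 13.2% of the same sum on day 6 and 10.7% in MEF, and 3.26% to 4.13% elsewhere. The labels give strain A12 (Mbd3 flox/-) for MEF and iPSC, B6/129 for day 6 and both OSKM NSC libraries and BDF2 for brain NSC, so strain cannot be told apart from the groups that differ in it. MEF, iPSC and ESC had transcripts of the Y-linked gene Eif2s3y at 114, 90.9 and 103 RPKM, the other 4 libraries had no Eif2s3y read, and Xist, the RNA that silences an X chromosome, stood at 447 RPKM in brain NSC and at 0.0140 to 4.56 RPKM elsewhere.

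The levels of the 4 reprogramming factors were compared across all libraries. Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, mm10) stood at 1.09 RPKM in MEF, 886 on day 6, 3.13 in Tomato-positive and 1.32 in Tomato-negative OSKM NSC, 1.55 in brain NSC, 2067 in iPSC and 1410 in ESC. Sox2 (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461) stood at 2.92 RPKM in MEF, 65.4 on day 6, 116 and 120 in the OSKM NSC libraries, 201 in brain NSC, 252 in iPSC and 183 in ESC. Klf4 (ENSMUSG00000003032) stood at 15.1 RPKM in MEF, 82.7 on day 6, 3.52 and 4.97 in the OSKM NSC libraries, 7.90 in brain NSC, 143 in iPSC and 75.2 in ESC. Myc (ENSMUSG00000022346) stood at 21.1 RPKM in MEF, 179 on day 6, 90.5 and 68.5 in the OSKM NSC libraries, 42.3 in brain NSC, 11.3 in iPSC and 1.22 in ESC. These gene levels take all exons together and do not separate the OSKM transgene from the endogenous gene. Single exons differed, and which source their reads had was not tested. The Klf4 exon at 55531867 to 55532453 on chromosome 4 stood at 1.44 RPKM on day 6, 5.26 in MEF and 51.8 in iPSC, whereas the exon at 55529718 to 55529882 stood at 339 RPKM on day 6, 40.8 in MEF and 312 in iPSC.

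**Figure D1:**
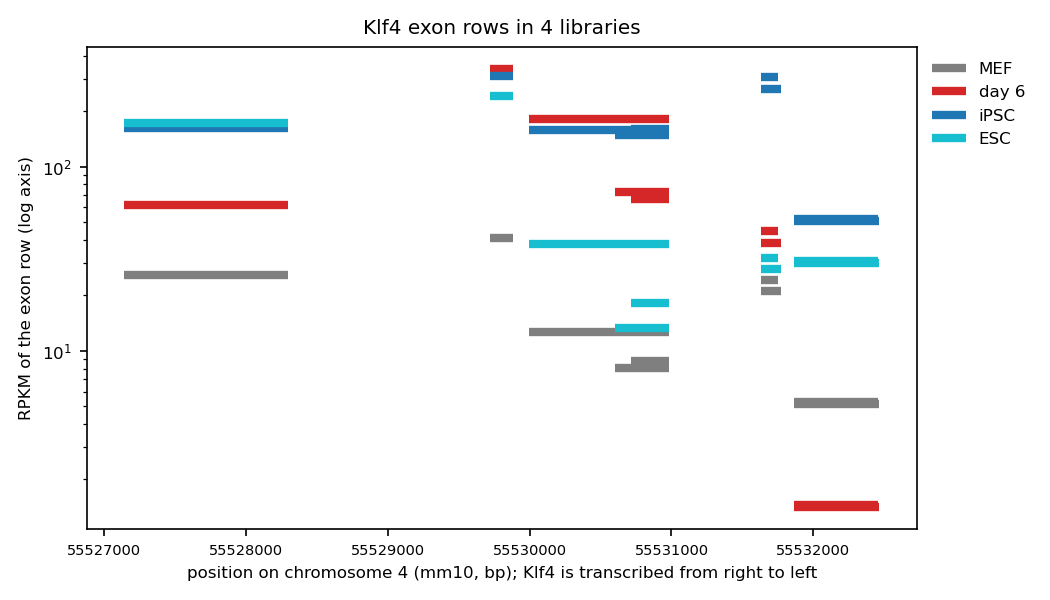
Level of each Klf4 exon (RPKM, log axis) along chromosome 4 (mm10, base pairs) in 4 libraries, 1 library per group. The exon at 55531867 to 55532453 is lower on day 6 than in MEF, and the exon at 55529718 to 55529882 is near the iPSC level.

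Nanog (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), a core gene of naive pluripotency, stood at 0.795 RPKM in MEF, 67.2 on day 6, 5.27 in Tomato-positive and 1.37 in Tomato-negative OSKM NSC, 0.154 in brain NSC, 772 in iPSC and 765 in ESC. Olig2 (ENSMUSG00000039830, chromosome 16, 91225457 to 91228677), a transcription factor of neural progenitors, stood at 262 RPKM in Tomato-positive and 474 in Tomato-negative OSKM NSC and at 342 in brain NSC, against 0.0508 in MEF, 0.323 on day 6, 0.0409 in iPSC and 2.26 in ESC. Nes, which encodes the intermediate filament nestin, stood at 22.8 RPKM in MEF, 34.9 on day 6, 225 and 451 in the OSKM NSC libraries, 123 in brain NSC, 5.65 in iPSC and 6.42 in ESC. Pax6 stood at 2.36, 2.05, 6.92, 14.7, 19.9, 0.235 and 0.101 RPKM in the same order of libraries. Col1a1, the main collagen gene of fibroblasts, stood at 9085 RPKM in MEF, 15.0 on day 6, 123 in Tomato-positive and 10.7 in Tomato-negative OSKM NSC, 0.700 in brain NSC, 19.0004 in iPSC and 291 in ESC. Thy1, a fibroblast surface marker, stood at 583 RPKM in MEF, 8.04 on day 6, 89.3 in Tomato-positive and 15.0 in Tomato-negative OSKM NSC, 0.833 in brain NSC, 5.80 in iPSC and 158 in ESC. Mbd3, a subunit of the NuRD repressor complex, stood at 65.3 RPKM in MEF, 136 on day 6, 271 and 206 in the OSKM NSC libraries, 170 in brain NSC, 68.4 in iPSC and 73.6 in ESC. The labels give Mbd3 flox/- for MEF and iPSC, so this genotype cannot be told apart from other differences of those libraries.

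**Figure D2:**
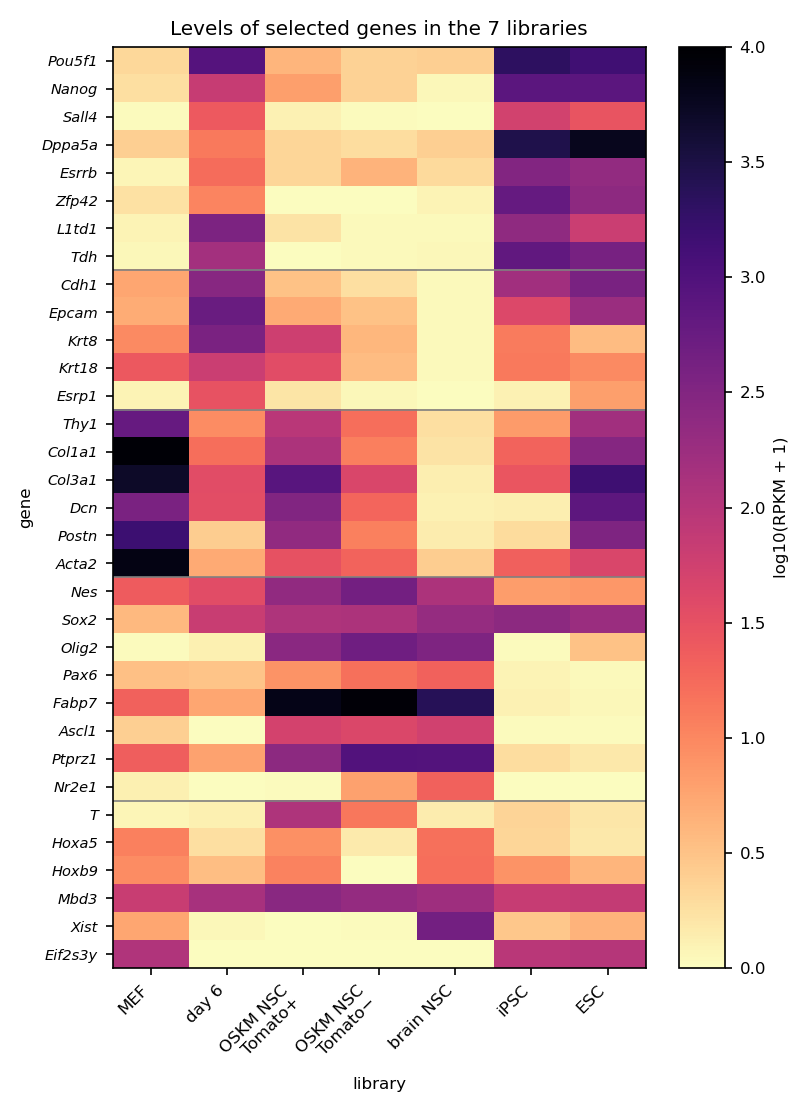
Levels of selected genes in the 7 libraries (color, log10 of RPKM plus 1; genes run down and libraries across, 1 library per group). Pou5f1 reaches 886 RPKM on day 6 and lies at 3.13 RPKM or below in the OSKM NSC libraries and brain NSC, where Olig2 lies at 262 RPKM or above.

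Across genes at or above 2 RPKM in any library, the OSKM NSC libraries correlated most with each other (Pearson r across genes 0.954) and Tomato-negative OSKM NSC correlated with brain NSC at 0.945. Tomato-positive OSKM NSC correlated with brain NSC at 0.895. Day 6 correlated with iPSC at 0.834, ESC at 0.826, Tomato-positive OSKM NSC at 0.825, Tomato-negative at 0.779 and MEF at 0.739. Tomato-positive OSKM NSC also correlated more than Tomato-negative with MEF (0.835 against 0.772), iPSC (0.789 against 0.750) and ESC (0.786 against 0.733). The iPSC and ESC libraries correlated at 0.929, and the lowest of the 21 values was 0.696 between brain NSC and ESC. Genes are not independent replicates, so these values carry no p-value.

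**Figure D3:**
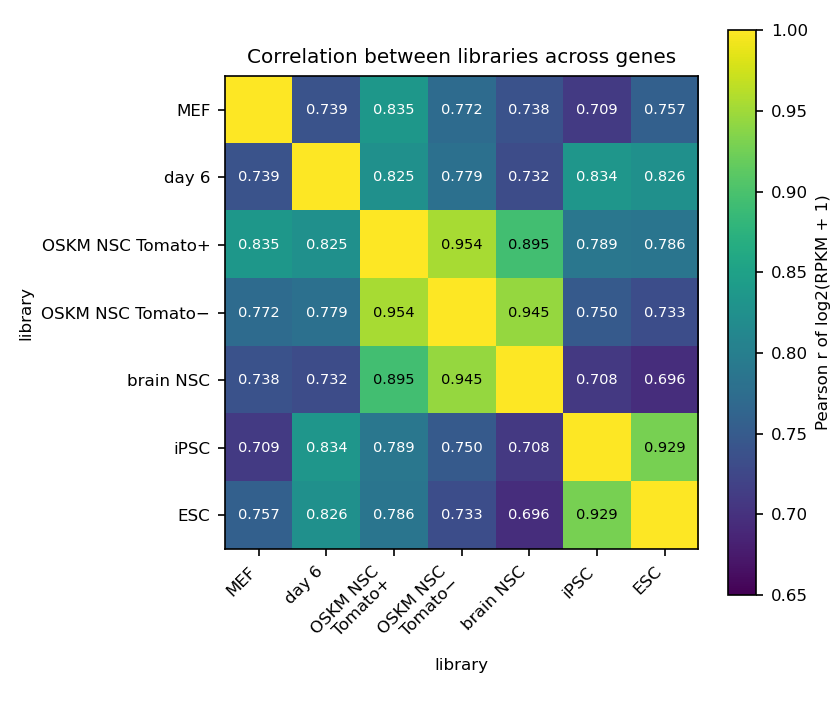
Pearson correlation across genes between each pair of the 7 libraries (color and printed value). The NSC libraries form a block with values of 0.895 to 0.954. Day 6 has values of 0.834, 0.826 and 0.825 with iPSC, ESC and Tomato-positive OSKM NSC, and 0.779 with Tomato-negative OSKM NSC.

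The comparison of day 6 with MEF sets the sorted intermediate beside fibroblasts of another strain and with Y-linked reads, so it also holds differences of strain and animal. Of 16154 genes, 1330 were at least 4-fold higher on day 6 and 2607 at least 4-fold lower. All 20 measured epithelial genes were at least 2-fold higher on day 6 (median log2 ratio 4.32), among them Epcam at 559 against 3.94 RPKM, the E-cadherin gene Cdh1 at 275 against 4.46 RPKM, Ap1m2 and the protease gene St14. Of 28 fibroblast and mesenchymal genes 27 were lower (median −6.35), including Acta2 at 4.05 against 7058 RPKM, Postn at 1.60 against 1492, Tagln at 6.68 against 3649 and Col1a1. All 19 measured general pluripotency genes were higher (median 3.18), with L1td1 at 354 against 0.213 RPKM, Tdgf1 at 51.0 against 0.196 and Zscan10 at 27.5 against 0.116. Of 16 naive pluripotency genes 13 were higher and 1 lower (median 2.98), with Tdh, Nanog, Fgf4 and Nr5a2 at 149, 67.2, 36.5 and 37.3 RPKM on day 6. The general list holds Pou5f1 and Sox2 and the naive list Klf4, whose levels can include the transgene. Among random lists of the same size and mean level, the medians of the epithelial and both pluripotency lists lay at percentile 100 and that of the mesenchymal list at 0. The 95% interval of the read ratio was 604 to 980 for Pou5f1 and 67.0 to 105 for Nanog.

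The genes highest on day 6 relative to MEF were replication-dependent histone H2A genes. Hist1h2ap and Hist1h2ao led at 4150 and 4498 RPKM against 1.80 and 2.04 RPKM, followed by Hist1h2ag and Hist1h2ab at 1888 and 1459 RPKM. In the same library Gm42418 took 8.82% of the summed exon reads, against 0.0258% in MEF. Ly6g6c, which encodes a small surface protein, stood at 1242 against 0.317 RPKM. The genes lowest on day 6 relative to MEF included genes of macrophages and neutrophils. Lyz2 stood at 0.0542 RPKM against 2098 RPKM in MEF, with a 95% interval of the read ratio of 5.98e-06 to 0.000178, and S100a8, S100a9 and Lilrb4a stood at 768, 761 and 683 RPKM in MEF with no read on day 6. Of 12 microglia and leukocyte genes 11 were lower on day 6 (median −5.12), including Tyrobp at 524 RPKM in MEF, and all 7 measured muscle genes were lower (median −4.63), including Acta1 at 122 RPKM in MEF. Transcripts of these other cell types were part of the MEF library in each comparison with MEF. All 4 reprogramming factors and 12 of 16 proliferation genes were higher on day 6, with Mcm2 at 178 against 27.1 RPKM, and none of either list was lower.

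Genes of the remaining lists split as follows between day 6 and MEF. Of 32 Hox cluster genes 23 were lower and none higher (median −1.42), with Hoxc8 at 0.278 against 14.2 RPKM. Of 16 neural stem cell genes 3 were higher and 10 lower, with Tnc at 1.21 against 543 RPKM. Sox2, whose level can include the transgene, was among the higher. Of 7 astrocyte genes 6 were lower, as were 6 of 8 oligodendrocyte lineage genes and 3 of 5 forebrain regional genes. Of 8 neuron genes 5 were higher and 1 lower, with the neurofilament gene Nefl at 97.3 against 2.30 RPKM and the growth cone gene Gap43 at 0.337 against 64.5. Of 6 keratinocyte and trophoblast genes 5 were higher and 1 lower, with Krt14 at 391 against 25.8 RPKM and Elf5 at 20.0 RPKM against no read. Of 19 imprinted genes 11 were lower and 4 higher (median −2.58), with H19 at 42.2 against 18104 RPKM and Igf2 at 4.40 against 3008. Of 16 glycolysis genes 9 were lower and 1 higher (median −1.15), with Aldoa at 848 against 3401 RPKM. Of 11 interferon response genes 7 were lower. Of 13 Mbd3-NuRD genes 4 were higher, with Hdac1 at 104 against 9.56 RPKM. The 5 sex-linked genes were all lower. Of 7 neural crest genes 3 were higher and 4 lower, of 6 primed epiblast and germ layer genes 2 and 3, of 3 germ line genes 2 and 1, of 4 midbrain and anterior hindbrain regional genes 1 and 1, of 4 endothelial genes 1 and 1, of 11 cell cycle inhibitor and p53 target genes 1 and 4, and of 12 immediate early and heat shock genes 1 and 2.

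**Figure D4:**
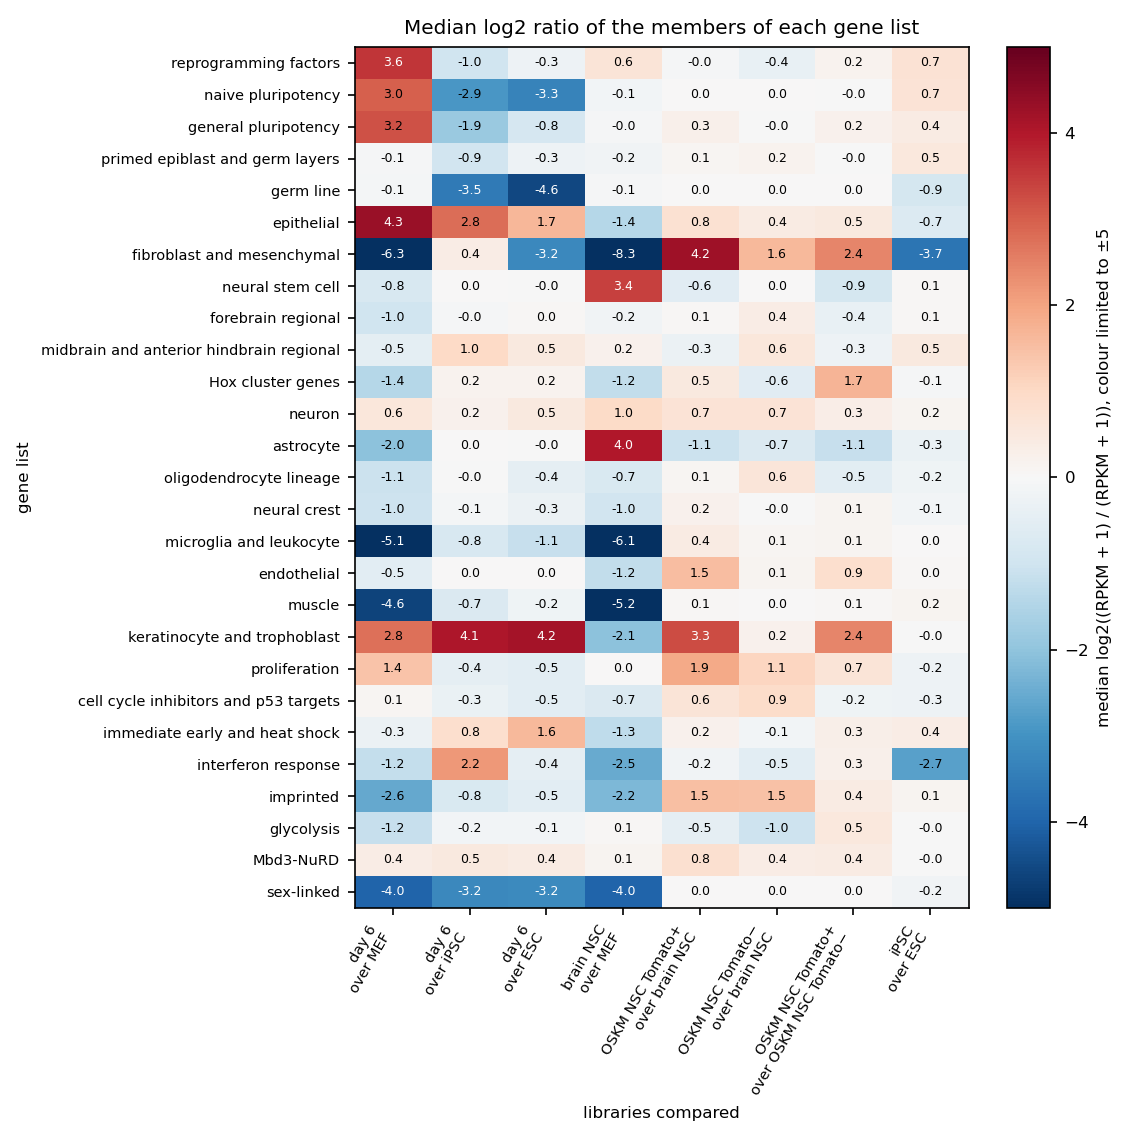
Median log2 ratio over the members of each fixed gene list (color, limited to ±5, and printed value; lists run down and 8 pairs of libraries across). Epithelial genes (median 4.32) and fibroblast genes (median −6.35) lie at opposite ends in day 6 against MEF.

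The comparison of day 6 with ESC and iPSC asks how near the sorted intermediate was to pluripotent cells. Of 15211 genes, 573 were at least 4-fold higher and 1105 at least 4-fold lower on day 6 than in ESC and in iPSC. All 11 measured germ line genes were lower, with Dazl at 0.0812 RPKM against 146 in iPSC and 246 in ESC and Sohlh2 at 2.87 against 155 and 168. Of 18 naive pluripotency genes 12 were lower and none higher, with Klf2 at 0.753 RPKM against 109 and 51.6, and with Tcl1, Prdm14 and Zfp42 among them. Of 20 general pluripotency genes 9 were lower and 1 higher, with Dppa5a at 12.3 RPKM against 2867 and 5932 and Dnmt3l at 0.239 against 23.0 and 28.3. The X-linked homeobox genes Rhox2b and Rhox3c stood at 241 and 220 RPKM in iPSC and 309 and 335 in ESC, with 0.0544 RPKM and no read on day 6. Nanog stood at 67.2 RPKM against 772 and 765. Upp1, the uridine phosphorylase gene, was the gene lowest relative to both, at 0.491 RPKM against 454 and 534.

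Epithelial genes were higher on day 6 than in the pluripotent lines. Of 20 measured, 14 were higher than in both references and 1 lower, with Krt8 at 365 RPKM against 11.7 and 2.62, Krt19 at 261 against 5.33 and 9.33, and Cldn3 and Dsp. Of 6 keratinocyte and trophoblast genes 5 were higher, with Krt14 at 391 RPKM against 5.01 in iPSC and 4.75 in ESC. Besides H2A genes, the genes highest on day 6 were Ly6g6c at 1242 RPKM, Aldh3a1, an aldehyde dehydrogenase gene, at 847 RPKM against 0.590 and 0.683, and Esp15 at 535 RPKM against 0.0294 in iPSC and no read in ESC. Myc, whose level can include the transgene, was higher than in both references. ESC carried mesenchymal transcripts, with Col3a1 at 1477 RPKM against 26.9 in iPSC, and against iPSC alone 1022 genes were higher on day 6. Against ESC alone 2028 genes were lower on day 6.

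The pluripotent references differed from MEF in 1282 genes that were at least 4-fold higher in both and 1553 that were lower in both, of 16287. All 20 general pluripotency genes and 17 of 18 naive pluripotency genes were higher, led by Dppa5a, Pou5f1, Nanog, Tdh, Fbxo15 and Tdgf1. Dppa5a stood at 2867 RPKM in iPSC and 5932 in ESC against 1.54 in MEF, and Tdh, a threonine dehydrogenase gene, at 664 and 401 against 0.154. All 11 germ line genes, 12 of 18 epithelial genes and 11 of 16 proliferation genes were higher. Of 28 mesenchymal genes 24 were lower in both, with Tagln at 22.7 and 19.4 against 3649 RPKM, and 28 of 33 Hox cluster genes were lower and 1, Hoxc13, higher. Among the genes lowest in both were Arg1 and S100a9, which stood at 861 and 761 RPKM in MEF, the elastin gene Eln at 1548 RPKM and Dlk1 at 283 RPKM. With ESC alone 1933 genes were higher than in MEF, and with iPSC alone 2351 were lower. Under median-of-ratios scaling, 35.2% of the genes past 4-fold were higher, against 45.2% as deposited.

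Brain NSC gave the reference for the intended product. Of 16253 genes, 1177 were at least 4-fold higher and 2161 at least 4-fold lower than in MEF. Of 28 neural stem cell genes 24 were higher and 1 lower (median log2 ratio 3.43). Olig2 stood at 342 RPKM, Olig1 at 320 RPKM against no read, Bcan, a brain proteoglycan gene, at 711 against 1.20 and Ncan at 369 against 1.48. Of 9 astrocyte genes 6 were higher and 1 lower (median 3.99), with the glutamate transporter gene Slc1a3 at 1936 against 16.2 RPKM. The GABA transporter gene Slc6a11 was the gene highest relative to MEF, at 792 against 0.0272 RPKM. Of 28 mesenchymal genes 26 were lower and 1 higher (median −8.27), with Col1a2 at 0.482 against 10202 RPKM and Col3a1 at 0.366 against 4949. The imprinted genes H19 and Igf2 stood at 1.58 and 0.244 RPKM against 18104 and 3008, and 14 of 18 imprinted genes were lower. All 12 microglia and leukocyte genes and all 7 muscle genes were lower than in MEF, and 10 of 11 interferon response genes were lower. No proliferation gene passed 2-fold. Under scaling to equal totals, 45.3% of the genes past 4-fold were higher, against 35.3% as deposited.

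The OSKM NSC libraries were compared with the same MEF library, which is of another strain and is not their source. At least 4-fold differences from MEF in both libraries were found in 634 genes higher and 1274 lower, of 15921. Of 26 neural stem cell genes 19 were higher in both and none lower. Olig1 stood at 372 RPKM in Tomato-positive and 730 in Tomato-negative OSKM NSC against no read in MEF, and Fabp7, a lipid-binding protein of radial glia, at 6511 and 8761 against 19.6. Rfx4 stood at 112 and 208 against 0.418. Of 28 mesenchymal genes 22 were lower in both and 1 higher, with Acta2 at 30.1 and 18.9 against 7058 RPKM. All 12 microglia and leukocyte genes, all 7 muscle genes and all 10 interferon response genes were lower, with Lyz2 at 9.06 and 0.150 against 2098 RPKM and Oas1a at 0.279 and 0.0632 against 23.0. Of 16 proliferation genes 10 were higher. Tomato-positive OSKM NSC alone had 1032 genes higher than MEF, and Tomato-negative OSKM NSC alone had 1158 higher and 1951 lower. Under median-of-ratios scaling 402 genes were higher, or 19.2% of those past 4-fold, against 33.2% as deposited.

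The OSKM NSC libraries were also compared with day 6, the intermediate of the conversion. Of 15418 genes, 1394 were at least 4-fold higher and 853 at least 4-fold lower in both OSKM NSC libraries. Of 24 neural stem cell genes 21 were higher and none lower, with Fabp7 at 6511 and 8761 against 4.47 RPKM and Tnc at 819 and 455 against 1.21. Astrocyte genes were higher in 6 of 7, with Sparcl1 at 449.8 and 679 RPKM against 0.0158. With 2 Sparcl1 reads on day 6 the 95% intervals of the read ratio were wide, 7613 to 227126 and 11463 to 341932. All 14 naive pluripotency genes were lower, as were 16 of 19 general pluripotency genes and 19 of 20 epithelial genes, with Tdh, L1td1, Epcam, St14 and Cdh1 among them. Epcam stood at 4.08 and 2.21 RPKM against 559. Of 20 imprinted genes 6 were higher and 7 lower, with Mest and Nnat among the higher, Mest at 1553 and 1522 against 12.1 RPKM. No proliferation gene passed 2-fold in both. The H2A genes, Ly6g6c and Aldh3a1 headed the genes that were lower. Tomato-negative OSKM NSC alone had 1330 genes lower than day 6. Under median-of-ratios scaling 48.3% of the genes past 4-fold were higher, against 62.04% as deposited.

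OSKM NSC were compared with brain NSC to see how the product differed from its primary counterpart. In both libraries 310 genes were at least 4-fold higher and 173 at least 4-fold lower than in brain NSC, of 14712. Of 28 neural stem cell genes 3 were higher in both libraries and 2 lower, with Prom1 at 29.5 and 6.60 against 0.156 RPKM and Nr2e1, which encodes the stem cell receptor TLX, at 0.0724 and 5.17 against 19.6. Of 22 mesenchymal genes 17 were higher and none lower, with Col3a1 at 810 in Tomato-positive and 43.7 in Tomato-negative OSKM NSC against 0.366 RPKM, and Mmp2 at 178 and 33.8 against 0.169. Of 16 imprinted genes 12 were higher and none lower, with H19 at 471 and 76.5 against 1.58 RPKM. Of 16 proliferation genes 9 were higher and none lower, with Tyms at 75.4 and 39.7 against 7.85 RPKM. The developmental gene T (Brachyury, ENSMUSG00000062327, chromosome 17, 8434423 to 8442496) stood at 115 and 12.6 against 0.425 RPKM. Tagln2 and Gas6 were the genes highest relative to brain NSC, with Tagln2 at 464 and 321 against 0.510 RPKM.

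Among genes lower than in brain NSC, Xist was first, followed by the X-linked genes Ott and Luzp4 at 40.7 and 37.3 RPKM in brain NSC and at 0.0498 RPKM or below in the OSKM NSC libraries. Gpr37l1 and the tau gene Mapt were also among the lowest, with Mapt at 5.12 and 5.04 against 122 RPKM. Of 9 astrocyte genes 4 were lower in both and 1 higher, with the glutamate transporter gene Slc1a2 at 1.92 and 21.4 against 135 RPKM. The Tomato-positive library carried mesenchymal and keratin transcripts, and alone it had 1083 genes higher and 461 lower than brain NSC. Without it, Tomato-negative OSKM NSC alone had 464 higher and 234 lower.

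The comparison with the pluripotent references asks which pluripotency genes the OSKM NSC libraries expressed. Relative to ESC and iPSC together, 832 of 15517 genes were at least 4-fold higher in both OSKM NSC libraries and 998 at least 4-fold lower. Of 18 naive pluripotency genes 17 were lower, of 20 general pluripotency genes 17, of 18 epithelial genes 14, and all 11 germ line genes. Zfp42 and Fam25c had no read in either OSKM NSC library, against 617 and 736 RPKM in iPSC and 238 and 261 in ESC, and Dppa5a stood at 1.19 and 0.885 RPKM. Of 24 neural stem cell genes 21 were higher and none lower, with Ptprz1 at 249 and 935 RPKM against 0.880 in iPSC and 0.517 in ESC. Acsbg1, Gpm6a and the Notch glycosyltransferase gene Lfng were also among the genes highest in OSKM NSC. Against iPSC alone 1294 genes were higher in OSKM NSC, and against ESC alone 1622 were lower. Tomato-negative OSKM NSC alone had 1310 genes higher than both references.

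The Tomato-positive and Tomato-negative OSKM NSC libraries compare cells with and without the record of Nanog expression. In 15323 genes, 425 were at least 4-fold higher and 135 at least 4-fold lower in Tomato-positive cells. Of 28 mesenchymal genes 25 were higher and 1 lower in Tomato-positive cells (median log2 ratio 2.43), with Thbs2 at 87.9 against 0.746 RPKM, S100a4 at 269 against 9.46, and Col6a1 and Col6a2. Keratin genes of chromosome 15 headed the list, with Krt6b at 134 against 0.0851 RPKM, Krt6a at 127, and Krt5, Krt74 and Krt72 at 75.8, 75.3 and 63.1 RPKM against no read. All 3 measured keratinocyte and trophoblast genes and 5 of 7 epithelial genes were higher, with Krt8 at 57.8 against 3.05 RPKM. Krt5 and Krt6a are among the former, so that count is not separate from the keratin genes above. Of 20 Hox cluster genes 18 were higher and none lower (median 1.68), with Hoxa7 at 10.5 against 0.0190 RPKM and Hoxb9 at 9.98 against no read. The gene T stood at 115 against 12.6 RPKM.

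Of 28 neural stem cell genes 11 were lower and 1 higher in the Tomato-positive library (median −0.86), with Bcan at 65.8 against 496 RPKM, Nr2e1 at 0.0724 against 5.17, Lhx2 and Egfr, and 5 of 10 astrocyte genes were lower and none higher. Of 13 neuron genes 3 were higher and 2 lower. The potassium channel gene Kcna2 and the sodium pump gene Atp1a4 were among the lowest, with Kcna2 at 1.82 against 77.8 RPKM. Of 16 imprinted genes 7 were higher and 1 lower, with Dlk1 at 58.7 against 2.84 RPKM. Of 6 measured naive pluripotency genes 2 were higher, Nanog among them, and 1 lower. With the pseudocount of 1, none of Pou5f1, Sox2, Klf4 and Myc passed 2-fold, Pou5f1 standing at 3.13 against 1.32 RPKM, a ratio of 2.38 without the pseudocount (read ratio interval 1.62 to 2.81). Under scaling to equal totals 262 genes were lower and 54.7% of the genes past 4-fold were higher, and under median-of-ratios scaling 63.7% were higher, against 75.9% as deposited.

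The iPSC and ESC references differed from each other in 203 genes that were at least 4-fold higher in iPSC and 691 at least 4-fold lower, of 15749. The Nanog levels were 772 and 765 RPKM. Mesenchymal genes were lower in iPSC in 22 of 27 (median −3.67), with Dcn at 0.363 against 741 RPKM, Lum at 0.0493 against 308 and Postn at 0.957 against 340. The labels put both lines on MEF feeders, with a question mark for iPSC. Of 10 interferon response genes 7 were lower in iPSC, with Isg15 at 0.251 against 36.9 RPKM, and Saa3, an acute phase gene, had no read in iPSC against 1230 RPKM in ESC. Hprt, an X-linked purine salvage gene, stood at 0.669 RPKM in iPSC and 549 in ESC, with a 95% interval of the read ratio of 0.000904 to 0.00161. The Nodal pathway genes Lefty1, Lefty2 and Nodal were higher in iPSC, with Lefty1 at 55.1 against 2.27 RPKM. Of 12 germ line genes 6 were lower in iPSC, with Tdrd12 at 7.58 against 142 RPKM, and of 18 naive pluripotency genes 5 were higher and 3 lower, with Dppa3 at 4.08 against 41.6 RPKM. Under scaling to equal totals 34.0% of the genes past 4-fold were higher, against 22.7% as deposited.

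Genes that stood apart on day 6 were counted against MEF, which is of another strain, and both OSKM NSC libraries. Those at least 4-fold higher on day 6 than in MEF and in both OSKM NSC libraries numbered 584, and 700 were at least 4-fold lower than in all 3. Of these, 271 were also at least 4-fold higher on day 6 than in ESC, iPSC and brain NSC, and 97 were lower than in those. The genes higher on day 6 alone were led by Hist1h2ao, Hist1h2ap, Ly6g6c, Esp15 and Aldh3a1, with log2 ratios of 8.98 or more against the nearest library. Those lower on day 6 alone were led by Npl, Fxyd6, Atp1b2 and the actin-binding gene Cotl1, with Fxyd6 at 1.63 RPKM on day 6 and at 53.2 RPKM or above in the other libraries. Among genes lower on day 6 than in MEF and both OSKM NSC libraries were Tnc, Ptn, Plat, Igfbp3 and Igfbp5, with Igfbp5 at 0.391 RPKM on day 6 and at 87.2, 163 and 96.9 RPKM in MEF and the OSKM NSC libraries.

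The share of reference differences from MEF that the day 6 and OSKM NSC libraries shared was counted at 2-fold. Of the 1282 genes higher in the pluripotent lines than in MEF, 659 (51.4%) were higher on day 6 than in MEF, and of the 1553 lower genes 1429 (92.0%) were lower. If the lists were independent, 287 and 485 would be shared. Such numbers here use the rate over all genes at 2 RPKM in MEF or the library. These include genes too low in MEF to be lower, so the numbers for lower genes are too small. Tomato-positive and Tomato-negative OSKM NSC shared 36.1% and 31.1% of these higher genes (463 and 399, where independence gives 345 and 313) and 69.9% and 75.4% of the lower ones (1086 and 1171, where independence gives 269 and 331). Of the 1177 genes higher in brain NSC, 870 (73.9%) were higher in Tomato-positive and 1035 (87.9%) in Tomato-negative OSKM NSC, where independence gives 317 and 287. Of the 2161 lower genes, 1764 (81.6%) and 2001 (92.6%) were lower, where independence gives 375 and 461. Day 6 shared 305 (25.9%) of the higher brain NSC genes and had 221 in the opposite direction, and shared 1647 (76.2%) of the lower ones and had 143 in the opposite direction, where independence gives 263 and 674. The same MEF library is the control of both sides, so part of the excess over independence may come from it. Its transcripts of other cell types, such as macrophages and muscle, can be lower in every library compared with it. An unchanged library drawn from the MEF reads shared 0.0779% of the pluripotent higher genes with counting noise alone, 0.662% with a dispersion of 0.04 and 11.9% with 0.16, and 0.777% and 15.2% of the lower genes with those dispersions. Against the brain NSC list it shared 13.1% of the higher and 13.48% of the lower genes with a dispersion of 0.16.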

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

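No test was chosen for these results after they were seen. The exons without a match in the annotation are data that no comparison uses, and 6013 of the 9084 reached 2 RPKM in at least 1 library. They held 3.94% of the summed exon RPKM in MEF and 4.62% in iPSC, with the other libraries between.

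Relative to brain NSC, 22 of 15739 genes were at least 2-fold on opposite sides in the OSKM NSC libraries, which is a difference between the Tomato-positive and Tomato-negative groups that was not tested. Of these, 9 were higher in Tomato-positive and 13 in Tomato-negative OSKM NSC. The genes named here were chosen after their values were seen: the membrane protein gene Emp1 stood at 237 RPKM in Tomato-positive, 7.29 in Tomato-negative OSKM NSC and 15.95 in brain NSC, the fibronectin gene Fn1 at 338, 24.2 and 59.7, and Cd93 at 5.43, 110 and 14.2.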

How the results depend on the processing

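The settings that leave out a library or keep exons that do not overlap were chosen after seeing the data. No paired analysis was possible because each group has 1 library and nothing pairs them. No direction reversed among the named genes and the list medians of 2-fold or more, but smaller list medians could change sign. Under median-of-ratios scaling 48.3% of the genes past 4-fold between OSKM NSC and day 6 were higher, against 62.04% as deposited. Of the gene counts, 175 values stayed within 1.5 times the main count and 53 did not. For day 6 sets these numbers were 32 and 8, for shares 38 and 22 (against their 95% binomial interval), for correlations 171 and 39 (a change of 0.05), for list medians 4400 and 460 (a change of 0.5), and for named genes 2214 and 666 (against the read ratio interval). Not all of these values could move. The floor does not enter the list medians or the ratios of named genes. A named gene without a read ratio interval always counted as unmoved. A lower floor or none could not change gene counts, day 6 sets or shares. A 4-fold ratio with a pseudocount of 1 needs more than 2 RPKM in the higher library. The numbers of unmoved values therefore overstate how stable the results were. Causes of moves were not tested unless stated. Median-of-ratios scaling shifted log2 levels by 0.25 in MEF, 0.19 on day 6, −0.30 in Tomato-positive OSKM NSC and −0.12 in ESC, and equal totals by −0.17 in Tomato-positive, 0.26 in Tomato-negative OSKM NSC, 0.31 in brain NSC and −0.29 in ESC.

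With equal totals, 262 genes were lower in Tomato-positive than Tomato-negative OSKM NSC, and Tomato-positive OSKM NSC shared 64.2% of the higher and 84.9% of the lower brain NSC genes. With median-of-ratios scaling 402 genes were higher in OSKM NSC than MEF, and the shares were 62.5% and 88.0% in Tomato-positive and 85.6% and 93.9% in Tomato-negative OSKM NSC. With a pseudocount of 0.25, 486 genes were higher and 267 lower in OSKM NSC than brain NSC, 658 and 222 in Tomato-positive than Tomato-negative, 359 higher in iPSC than ESC, 1057 lower on day 6 than in MEF and both OSKM NSC libraries and 193 on day 6 alone. The shares were 56.1% of higher pluripotent genes on day 6, 79.8% of lower brain NSC genes in Tomato-positive and 90.6% in Tomato-negative OSKM NSC.

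A pseudocount of 4 shrinks ratios of low values. It gave 755 genes higher and 1556 lower on day 6 than MEF, 305 and 505 on day 6 than ESC and iPSC, 717 and 863 in ESC and iPSC than MEF, 653 and 1310 in brain NSC than MEF, 297 and 752 in OSKM NSC than MEF, 654 and 496 than day 6, 99 and 78 than brain NSC, 392 and 528 than ESC and iPSC, 172 and 53 in Tomato-positive than Tomato-negative, and 77 and 353 in iPSC than ESC. On day 6, 341 were higher and 269 lower than in MEF and both OSKM NSC libraries, and 161 and 32 on day 6 alone. The shares were 55.2% and 94.4% on day 6, 69.98% and 85.2% in Tomato-positive, and 95.9% of lower genes in Tomato-negative OSKM NSC.

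With a floor of 8 RPKM, 201 genes were higher in OSKM NSC than brain NSC, and the shares were 58.7% of higher genes on day 6, 77.8% and 83.9% in Tomato-positive, and 90.3% of higher genes in Tomato-negative OSKM NSC. With the highest exon of each gene, 2142 genes were higher on day 6 than MEF, 865 higher and 1809 lower on day 6 than ESC and iPSC, 1845 higher in brain NSC than MEF, 1162 higher in OSKM NSC than MEF, 2251 higher than day 6, 605 higher and 273 lower than brain NSC, 764 and 323 in Tomato-positive than Tomato-negative, 414 and 1273 in iPSC than ESC, 1305 lower on day 6 than in MEF and both OSKM NSC libraries and 350 lower on day 6 alone. The shares were 54.5% and 89.7% on day 6, and 77.1% and 89.9% of lower genes in Tomato-positive and Tomato-negative OSKM NSC.

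Without ESC, 1022 genes were higher on day 6, 2351 lower in iPSC than MEF and 1294 higher in OSKM NSC. Without iPSC, 2028 were lower on day 6, 1933 higher in ESC than MEF and 1622 lower in OSKM NSC. Without Tomato-positive OSKM NSC, 1158 were higher and 1951 lower than MEF, 1330 lower than day 6 and 1310 higher than ESC and iPSC. Without Tomato-negative OSKM NSC, 1032 were higher than MEF, and 1083 higher and 461 lower than brain NSC. Fewer libraries to pass in give larger counts by construction.

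Correlations moved by 0.05 or more only under a changed floor, which changes the genes compared. With a floor of 0.4 RPKM, MEF correlated with day 6 at 0.791, brain NSC at 0.792, iPSC at 0.768 and ESC at 0.809, brain NSC with day 6 at 0.783, iPSC at 0.765 and ESC at 0.759, and Tomato-negative OSKM NSC with iPSC at 0.79996 and ESC at 0.789. With a floor of 8 RPKM, MEF correlated with day 6 at 0.666, Tomato-negative OSKM NSC at 0.705, brain NSC at 0.663, iPSC at 0.629 and ESC at 0.688, day 6 with Tomato-negative OSKM NSC at 0.718 and brain NSC at 0.658, iPSC with Tomato-positive OSKM NSC at 0.733, Tomato-negative at 0.681 and brain NSC at 0.628, and ESC with these 3 at 0.726, 0.655 and 0.607. With no floor, MEF correlated with day 6 at 0.8499, Tomato-positive OSKM NSC at 0.9099, Tomato-negative at 0.875, brain NSC at 0.853, iPSC at 0.838 and ESC at 0.868. Day 6 then correlated with Tomato-positive OSKM NSC at 0.898, Tomato-negative at 0.872, brain NSC at 0.843, iPSC at 0.902 and ESC at 0.899, and Tomato-positive, Tomato-negative and brain NSC correlated with iPSC at 0.882, 0.859 and 0.833 and with ESC at 0.884, 0.853 and 0.8301. In all settings each library correlated best with the same other library.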

Other observations

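Tests chosen only after the result was seen are those of MEF-like cells, of male or Xist-expressing cells and of remaining day 6 cells for the mesenchymal genes, of cycling cells for the histone genes, and for chromosome X those over 810 genes and for each library apart. For kept RNA without a poly(A) tail and for a single X, the rules used were stricter than those written before the result.

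Of 11 measured immediate early and heat shock genes, 4 were higher on day 6 than in both pluripotent lines, none were lower and 7 did not pass 2-fold in both. In OSKM NSC relative to MEF, 7 of 12 neuron genes were higher and 1 lower, and 5 of 8 astrocyte genes were higher and none lower. Relative to brain NSC, all 5 measured epithelial genes were higher in both OSKM NSC libraries, and 4 of 11 cell cycle inhibitor and p53 target genes were higher and none lower. Rhox2b stood at 8.86 RPKM in Tomato-positive OSKM NSC, 0.120 in Tomato-negative, 241 in iPSC and 309 in ESC, with no read in brain NSC.

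Of 28 mesenchymal genes, 25 were higher and 1 lower in Tomato-positive than in Tomato-negative OSKM NSC. The tables argue against MEF-like cells mixed in as the whole source, since the excess over the Tomato-negative level, as a fraction of the MEF level, ran from 0.159% for Acta2 to 92.0% for Lum among the 26 genes with an excess, a ratio of 578.3 where 1 share of cells would give similar fractions. They argue against cells of a male or Xist-expressing animal, whose share had an upper limit of 0.0339%, and against remaining day 6 cells, in which the genes had a median log2 ratio of −3.007 to Tomato-positive OSKM NSC. A non-neural share of cells of the same line stays open: the neural stem cell genes had a median of −0.8649 but ran from −2.90 to 2.01. Clonal or regional identity of the line was not tested.

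Of 63 histone genes, 27 to 43 were at least 4-fold higher on day 6 than in each other library. As the whole source of this excess, a larger share of cycling cells is argued against relative to ESC, iPSC, Tomato-positive and Tomato-negative OSKM NSC. There the proliferation genes had median log2 ratios of −0.5395, −0.4464, −0.2946 (0.20 under median-of-ratios scaling) and 0.1744 (−0.06 under equal totals). Their upper quartile lay below the lower quartile of the histone genes, a gap that scaling leaves as it is. This gap does not test cycling cells as a part of the excess. Relative to Tomato-negative OSKM NSC the lower quartile of the proliferation genes was 0.08 as deposited, so most were higher on day 6. As the whole source, cycling cells stay open relative to MEF and brain NSC, where the medians were 1.418 and 1.662 and the quartiles overlapped. Shared reads between near-identical copies are argued against for the H1 genes, whose lowest median was 2.427, and how much of the H2A excess comes from shared reads was not settled. Kept RNA without a poly(A) tail was not settled. The rule written before the result took a class median under 2-fold as going against it. The lowest class median was under 2-fold, at 0.5391 log2 for H2B against brain NSC, but with quartiles of −0.07 and 1.84. Gm42418, a gene model over ribosomal RNA, took 8.82% of the summed exon reads on day 6 and at most 0.0657% elsewhere.

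Day 6 and both OSKM NSC libraries had no Y-linked read, and 6, 0 and 0 Xist reads over exons that do not overlap. The X median lay above all 19 autosome medians in none of the 4 pairs, over 810 X genes or over the 433 at the floor in every library. In Tomato-negative OSKM NSC 2 active X chromosomes are argued against, since the X median relative to the highest autosome median was −0.1057 log2 at the nearest in the gene sets, beyond its bootstrap spread in both. By this rule they stay open on day 6 (−0.1112) and in Tomato-positive OSKM NSC (−0.04016). There the upper bootstrap limit over the 433 genes passed the highest autosome, against iPSC and brain NSC. On day 6 it lay below the highest autosome in the other 3 combinations of reference and gene set. The upper limit of the X median relative to the autosome median was at most 0.232 on day 6 and 0.156 in Tomato-positive OSKM NSC. These values argue against a doubled X level relative to the references, and a smaller excess stays open. A single X met the rule written before the result, an X median not above all autosome medians. It stays open under the stricter rule that adds the bootstrap spread. The X median was at most −0.08531 relative to the autosome median over 810 genes and 0.1089 over 433. A second X silenced without Xist and strain were not tested.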
